A study of Mus musculus with 27 samples.

How the data were processed

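RNA sequencing measured gene expression in 27 libraries of sorted mouse bone marrow pre-DCs and of the cells grown from them. Per the labels, 3000 pre-DCs per well were cultured for 3 days with 2000 FSC from lymph nodes or with a cytokine, wells of a condition were pooled, and viable CD45 and CD11c positive cells were sorted by MHC class II. Libraries were made from amplified full-length cDNA, without molecular identifiers.

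The authors aligned reads with STAR, counted them per gene with HTSeq and tested pairs of groups with DESeq2 on mm10, with versions and options not stated. Each of the 36 deposited tables compares 1 pair of groups. The deposited tables hold counts per gene and library, and counts of a gene in a library were the same in every table that listed it (0 conflicts). The deposited signal values are normalized counts, which the authors made by dividing counts by 1 size factor per library. The authors' log2 fold changes were positive where the second-named group was higher, in 154502 of 154502 calls checked, and appear shrunk. The authors' p-value column is adjusted. The tables list nested gene sets of 14229 to 24777 genes, and 16063 genes were listed for all 27 libraries. Counts were used throughout, so deposited normalized counts, RPKM and fold changes entered no test, and an alternative pseudocount for normalized values did not apply.

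Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling). Low counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 14725 genes. One fit covered the 9 groups, with 18 residual degrees of freedom and Benjamini-Hochberg adjustment per comparison at 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Totals ranged from 9822686 to 17162595 counts per library. A count of 0 over a group was set to a floor of 3 counts over the group for lower bounds of folds. On simulated data the procedure found 52 of 100 genes planted with a log2 change of 1 and 79 of 100 with 2, each set of 100 with the right sign throughout, and 6 of 137 calls were false. It made 0 calls in an unchanged simulated comparison. Planted genes were drawn only from those above a minimum level in FLT3L HI cells, whose profile served for every group. Libraries were simulated without an effect of replicate number. These rates therefore do not cover genes at low levels or a structure by number.

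Groups, comparisons, 27 gene lists, named genes and most alternatives were chosen before the data were examined. The comparisons were HI against LO (mean of the cultures and each culture), LO and HI against the input, CSF1 against FLT3L, stroma (mean of mLN and pLN) against each cytokine, mLN against pLN, and differences of HI-LO effects between cultures. Named genes were the 5 with the largest and the 5 with the smallest log2 fold change among called genes with at least 16 CPM in the higher group and no overlap between libraries, up to 4 members of each list with the smallest adjusted p, and 8 genes throughout whether or not they passed. Symbols of predicted or unnamed genes, pseudogenes and immune receptor segments were left out, and not every gene that met the rule is named. Genes chosen later are named as such. Of the lists, 24 had at least 3 tested members and were tested with camera of limma 3.58.1 on voom values, with the preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of 1 comparison.

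Alternatives were RLE scaling, no filter on low counts, the replicate number as a block, DESeq2 1.42.0, a fit of only the libraries compared, and leaving out each library. Replicates 1 and 2 only was added after the data were seen. Replicate numbers are shared between groups, but the labels do not say what a number stands for.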

Results

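Pre-dendritic cells (pre-DCs), the bone marrow precursors of dendritic cells (DCs), were profiled by RNA sequencing as sorted (the input) and after 3 days of culture. The cultures contained FLT3L at 200 ng/ml, CSF1 at 50 ng/ml, or fibroblastic stromal cells (FSC) from mesenteric (mLN) or peripheral (pLN) lymph nodes, and each gave a population with low (LO) and a population with high (HI) surface MHC class II. The 9 groups held 3 libraries each, with 9822686 to 17162595 counts per library. Component 1 of the 27 libraries held 51.5% of the variance and separated HI from LO cells, with CSF1 LO libraries between them, and component 2, with 12.3%, separated the input from the cultured cells. Within groups, all 9 libraries numbered 3 lay on one side of the first component of the remaining variance and the 18 others on the other side, so each total of genes below is also given from replicates 1 and 2 only. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples. Errors beside log2 fold changes are standard errors of the edgeR model, and levels are mean CPM (counts scaled by the effective library total) ± SD over libraries. Floors for counts of 0 and intervals cover counting error only.

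**Figure D1:**
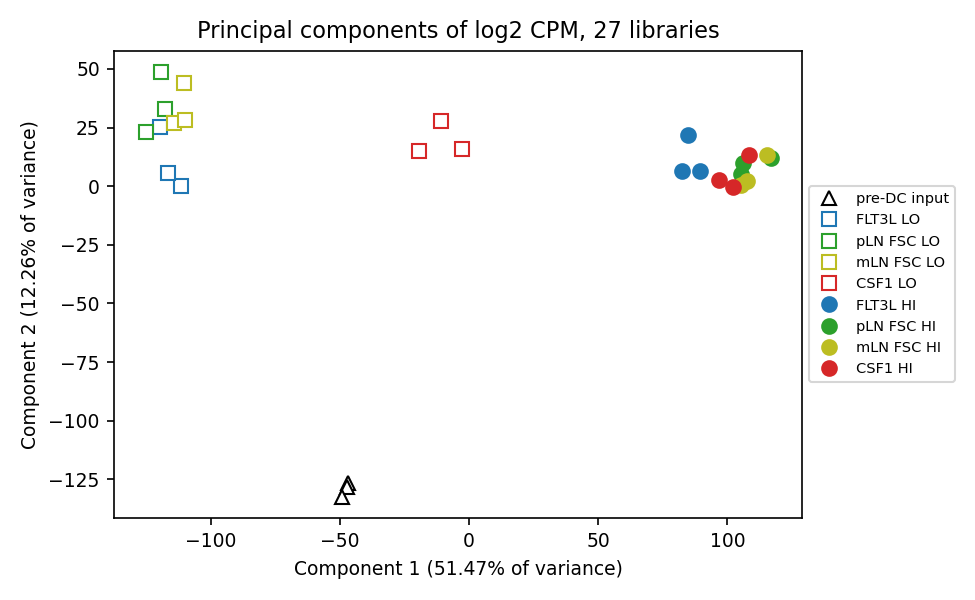
Principal components of log2 CPM, where each point is 1 of the 27 libraries, filled for HI, open squares for LO and open triangles for the input, and the axes give components 1 and 2 with their share of the variance (51.5% and 12.3%). HI and LO libraries of every culture lie apart along component 1.

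8 genes were fixed beforehand to be followed whether or not they passed, all protein coding and placed on GRCm38 (mm10). Not all of their values are printed below. Csf1r (ENSMUSG00000024621), which encodes the CSF1 receptor, lies on chromosome 18 from 61100598 to 61132149, and Flt3 (ENSMUSG00000042817), the FLT3L receptor gene, on chromosome 5 from 147330741 to 147400489. H2-Ab1 (ENSMUSG00000073421) encodes an MHC class II chain on chromosome 17 from 34257689 to 34269419, and Ccr7 (ENSMUSG00000037944), a homing receptor of mature DCs, lies on chromosome 11 from 99144196 to 99155077. The transcription factor genes were Zbtb46 (ENSMUSG00000027583, chromosome 2, 181387762 to 181459426), Irf8 (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694), Irf4 (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976) and Mafb (ENSMUSG00000074622, chromosome 2, 160363703 to 160367065). Of the Csf1r exonic bases, 15.1% are shared with Hmgxb3, and Lyz2, named often below, has a close paralog whose reads it may share.

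Averaged over the 4 cultures, HI cells differed from LO cells in genes of DC maturation, of plasmacytoid DCs and of the cell cycle, among others (12 libraries against 12). Ccr7 was higher in HI cells by 5.98 ± 0.20 on the log2 scale, and Ccl22, which encodes a chemokine of mature DCs, stood at 763 ± 399 CPM in HI and 0.624 ± 1.29 CPM in LO cells. Irf8, a transcription factor gene needed by several DC lineages, fell by 3.85 ± 0.07 from 5868 ± 1449 to 499.8 ± 399 CPM. Bst2 and Cox6a2, both abundant in plasmacytoid DCs, fell by 3.50 ± 0.06 and fell by 6.67 ± 0.22. Csf1r rose by 4.36 ± 0.22, and Lyz2, the lysozyme gene of monocytes and macrophages, rose by 3.93 ± 0.15.

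Of 26 tested DC maturation genes, 24 rose and 2 fell, and all 13 plasmacytoid DC genes fell (camera adjusted p = 2.07e-11 and 9.06e-12). Genes of DNA synthesis were higher in HI cells, among them Mcm5 (2.66 ± 0.09), with 20 of 21 S phase genes up and 1 down, and all 22 G2/M genes rose, including Ccna2 (2.51 ± 0.12) and Aurkb (2.52 ± 0.14). The G2/M list had an adjusted p = 0.0505 with an estimated correlation. Monocyte and macrophage genes rose in 20 of 26 cases and fell in 4, and lists of glycolysis (14 of 18 up, 2 down; Pkm 1.60 ± 0.04, Tpi1 1.79 ± 0.05) and of lipid handling (10 of 14 up, 2 down; Lpl 3.79 ± 0.23) also passed. Type I interferon genes such as Rtp4 (4.80 ± 0.33) rose in 14 of 19 cases and fell in 2, with an adjusted p = 0.518 with an estimated correlation. Immediate early and heat shock genes, which sorting can also induce, rose in 11 of 13 cases and fell in 2 (Atf3 4.96 ± 0.27; adjusted p = 0.149 with an estimated correlation), and 4 of 12 mitochondrially encoded genes fell in a list that did not pass (adjusted p = 0.172). Zbtb46, a factor of conventional DCs, rose by 4.37 ± 0.35, Irf4 rose by 0.84 ± 0.19, Mafb rose by 3.35 ± 0.53 and Flt3 fell by 1.74 ± 0.20. The Mafb mean rests largely on FLT3L, where LO cells had 0 counts. With CSF1 its log2 change was -1.54 ± 0.71 and with mLN FSC 1.64 ± 0.72, neither passing, and with pLN FSC 2.13 ± 0.75, which passed. Cathepsin genes moved in both directions, since Ctsd rose by 1.76 ± 0.05 while Ctsl fell by 2.99 ± 0.12. Parts of their exonic bases are shared with other genes (34.4% and 26.8%), as for Pkm (15.3%), Ccna2 (12.5%) and Cox6a2 (10.3%). H2-Ab1 was higher by 2.10 ± 0.14, but MHC class II defined the gates, so the H2 genes are no finding here. Adjusted over the list alone, the counts of these lists were equal or differed by 1 gene. In all, 9715 of 14725 genes passed an adjusted p of 0.05 (edgeR quasi-likelihood), 4850 higher and 4865 lower, and 9956 passed with replicates 1 and 2 only.

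**Figure D2:**
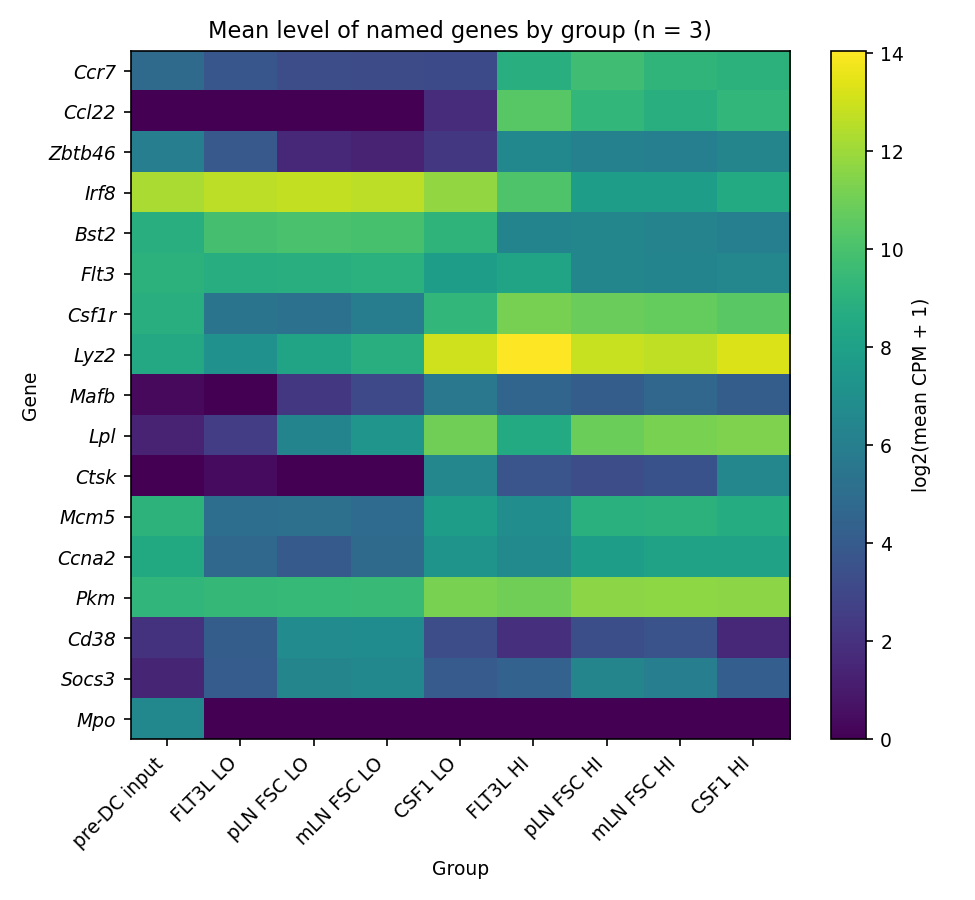
Level of 17 named genes in the 9 groups of 3 libraries, where the colour gives log2 of the mean CPM plus 1. Lyz2 stood at 138 CPM in FLT3L LO and 8482 CPM in CSF1 LO cells, and Cd38 was higher in both stromal LO groups than in either cytokine LO group.

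Within single cultures (3 libraries against 3) macrophage genes changed less with CSF1 and cell cycle genes changed more with stroma. Lyz2 went from 138 ± 17.0 CPM in LO to 17030 ± 847 CPM in HI cells with FLT3L, but from 8482 ± 662 to 10130 ± 836 CPM with CSF1. Csf1r rose by 5.83 ± 0.47 with FLT3L, by 4.78 ± 0.45 with mLN FSC and by 5.65 ± 0.47 with pLN FSC, against 1.18 ± 0.38 with CSF1. The CSF1 call for Csf1r (adjusted p = 0.0379) was lost without CSF1 LO replicate 1 (0.0697), 2 (0.0837) or 3 (0.140), or CSF1 HI replicate 1 (0.110) or 2 (0.107). Mcm5 rose by 4.20 ± 0.18 (mLN) and 3.76 ± 0.18 (pLN) with stroma, by 1.86 ± 0.17 with FLT3L and by 0.83 ± 0.16 with CSF1. Irf8 fell in all 4 cultures, by 2.51 ± 0.13 with FLT3L, by 3.20 ± 0.14 with CSF1, by 4.80 ± 0.15 with mLN FSC and by 4.90 ± 0.15 with pLN FSC.

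All 13 plasmacytoid DC genes fell in each of the 4 cultures, and at least 20 of 26 DC maturation genes rose in each. S phase genes that rose numbered 17 of 21 with FLT3L, 10 with CSF1 and 20 with either stroma, and the G2/M numbers were 19 of 22, 3, 21 and 21 (adjusted p = 0.0959, 0.171, 0.0559 and 0.0545 with an estimated correlation). Adjusted over the list alone, 14 S phase and 2 G2/M genes rose with CSF1. Ccr7 rose in every culture, by 5.16 ± 0.38 to 6.57 ± 0.41. Flt3 did not pass with FLT3L (adjusted p = 0.295), where it passed from replicates 1 and 2 only (0.0349). Mafb was at 0 counts in FLT3L LO and 22.9 ± 13.4 CPM in HI cells, at least 260.3-fold higher against a floor of 3 counts over the group, while with CSF1 it stood lower in HI (16.7 ± 10.95 CPM) than in LO cells (48.7 ± 13.04 CPM) without passing (adjusted p = 0.159). Genes called numbered 5302 with FLT3L (2838 higher), 2479 with CSF1 (993 higher), 7169 with mLN FSC (3713 higher) and 7131 with pLN FSC (3670 higher), or 5862, 3002, 7630 and 7553 from replicates 1 and 2 only.

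The HI-LO difference was tested between cultures. It differed between CSF1 and FLT3L for 1018 genes (212 with a larger log2 value under CSF1), with Lyz2 lower by 6.69 ± 0.43 on the log2 scale under CSF1, and all 18 monocyte and macrophage genes that passed went the same way, while Mcm5 differed by -1.03 ± 0.23. Between stroma and CSF1 it differed for 2279 genes (1596 with a larger value under stroma), among them Mcm5 (3.14 ± 0.20), with 20 of 21 S phase and 19 of 22 G2/M genes larger. Between stroma and FLT3L, a test added after the data were seen, it differed for 1328 genes (678 with a larger value under stroma), with 17 of 21 S phase and 15 of 22 G2/M genes larger, and Irf8 fell by 2.35 ± 0.15 more under stroma. Between mLN and pLN no gene passed in edgeR, with 586 at an unadjusted p under 0.05 and 35 called by DESeq2. Within replicates 1 and 2 these numbers were 1171, 2621, 1527 and 7.

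Compared with the input, cultured LO cells had lost cell cycle and progenitor transcripts and gained lysosomal and cholesterol synthesis transcripts (12 libraries against 3). All 22 G2/M genes fell, among them Ccnb2 (log2 fold change -4.38 ± 0.22), and 20 of 21 S phase genes fell, among them Mcm5 (-3.36 ± 0.11). Mpo, the myeloperoxidase gene of early myeloid cells, went from 93.1 ± 66.5 to 0.0132 ± 0.0307 CPM, and 10 of 11 myeloid progenitor genes fell while 1 rose. The protease gene Ctsl rose by 3.45 ± 0.22 with 20 of 23 lysosome genes up and 1 down, and Sqle (1.24 ± 0.09) and Hmgcr (1.31 ± 0.11) rose with 17 of 20 cholesterol synthesis genes and none down.

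Of the plasmacytoid DC genes, 10 of 13 rose and 1 fell, including Smim5 (3.34 ± 0.23) and Bst2 (0.93 ± 0.10). Ccr9, a chemokine receptor gene of plasmacytoid DCs and their precursors, rose by 6.57 ± 0.51 to 4287 ± 1235 CPM, with 21.5% of its exonic bases shared with other genes. Klf4 fell by 5.18 ± 0.34, Zbtb46 fell by 4.08 ± 0.42, Csf1r fell by 2.39 ± 0.27 as a mean and Ccr7 fell by 1.57 ± 0.24, whereas Irf8 (0.21 ± 0.10) and Irf4 (-0.02 ± 0.30) did not pass. Csf1r stood at 458.4 ± 126 CPM in the input and 631 ± 114.5 CPM in CSF1 LO cells, above the input, but at 36.8 to 61.2 CPM in the other LO groups. Flt3 did not pass (adjusted p = 0.327), and H2-Ab1 rose by 7.52 ± 0.36. Mafb stood at 0.302 ± 0.523 CPM in the input and 15.1 ± 21.3 CPM in LO cells, with 0 counts in FLT3L LO. It was not called by edgeR (adjusted p = 1) but was by DESeq2 (0.000891). The edgeR log2 change was 2.68 ± 246.77, an error so large that the missing call is no result. MHC class II genes rose in 10 of 13 cases and fell in 3, but the input was sorted as MHC class II negative, FLT3 positive and CD172a negative, so H2, Flt3 and Sirpa are no finding against it. Neutrophil genes fell in 7 of 9 cases (adjusted p = 0.243 with an estimated correlation), and in the input their levels ranged widely, S100a8 from 19.8 to 371.5 CPM. Single markers of other cells and of stress moved both ways. Of T cell genes, Cd4 rose by 6.93 ± 0.64 and Cd28 by 5.59 ± 0.39, but Lck fell by 2.58 ± 0.60 and Lat did not pass. Cd4 alone is therefore no sign of T cells. The stress gene Ier3 rose by 5.68 ± 0.42, while the red cell gene Hbb-bs went from 19.3 ± 26.8 to 0.0242 ± 0.0617 CPM. The heat shock gene Hspa1a went from 15.9 ± 5.23 to 0.190 ± 0.275 CPM. In total 5438 genes passed, 2516 higher and 2922 lower, and 5857 within replicates 1 and 2. Adjusted over the list alone, the cell cycle, progenitor, plasmacytoid and cholesterol counts were equal.

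HI cells against the input (12 libraries against 3) gained maturation, macrophage and lipid genes. Ccl22 was at 0 counts in the input and 763 ± 399 CPM in HI cells, at least 9600-fold higher against the floor of 3 counts over the group, and Mmp12, a macrophage elastase gene, reached 2779 ± 818 CPM, at least 34960-fold higher. Lpl, which encodes lipoprotein lipase, rose by 9.86 ± 0.61, and Lyz2 and Csf1r rose by 4.76 ± 0.30 and 1.97 ± 0.35. All 26 DC maturation genes rose, with Ccr7 up by 4.41 ± 0.34, and 12 of 13 plasmacytoid DC genes fell. Irf8 fell by 3.64 ± 0.08.

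Lysosome genes rose in 18 of 23 cases and fell in 2, led by Ctsd (3.84 ± 0.10) and Lipa (5.18 ± 0.23), and 17 of 20 cholesterol synthesis genes rose and 1 fell. Aldoa rose by 2.91 ± 0.10 among 9 of 18 glycolysis genes that rose, with 3 down. Lipid handling genes rose in 8 of 14 cases and fell in 2 (camera adjusted p = 0.00651). Monocyte and macrophage genes rose in 18 of 26 cases and fell in 4, and inflammatory genes rose in 13 of 16 and fell in 1. Of 21 S phase genes 15 fell (16 adjusted over the list alone) and of 22 G2/M genes 18 fell, including Ccnb2 (-1.70 ± 0.23), none rose, and the G2/M list had an adjusted p = 0.0902 with an estimated correlation. H2-Ab1 rose by 9.62 ± 0.39 and Flt3 fell by 2.14 ± 0.27, both used to sort the input. Mafb rose by 6.03 ± 0.92, Zbtb46 did not pass (0.30 ± 0.48), and Irf4 (0.81 ± 0.32, adjusted p = 0.0382) lost its call without input replicate 3 (0.224), pLN HI replicate 1 (0.0504) or 2 (0.0544), mLN HI replicate 1 (0.0507), CSF1 HI replicate 1 (0.0550) or 2 (0.0506), or FLT3L HI replicate 1 (0.0528). The median log2 change of all genes was -0.12, and changes are to be read relative to it. Adjusted over the list alone, 11 glycolysis, 20 macrophage and 14 inflammatory genes rose and 20 G2/M genes fell. In total 6876 genes passed, 2949 higher and 3927 lower, against 7325 in replicates 1 and 2.

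Among LO cells, CSF1 gave higher levels of macrophage, lipid and cell cycle transcripts than FLT3L (3 libraries against 3). Lyz2 was higher with CSF1 by 5.94 ± 0.34, Csf1r by 3.93 ± 0.43 and Adgre1, the F4/80 gene of macrophages, by 4.73 ± 0.44. Lpl was higher by 8.76 ± 0.59, and Pkm and Tpi1, which encode glycolytic enzymes, by 1.85 ± 0.08 and 2.36 ± 0.11. Mcm5 and Ccna2 were higher by 2.87 ± 0.17 and 2.61 ± 0.24. Cav1 was at 0 counts with FLT3L and 189 ± 74.8 CPM with CSF1, at least 2142-fold higher, and Mafb at least 553-fold higher at 48.7 ± 13.04 CPM.

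Higher with CSF1 were 18 of 26 monocyte and macrophage genes (2 lower), 19 of 21 S phase and 19 of 22 G2/M genes, 10 of 18 glycolysis genes, 7 of 14 lipid genes and 11 of 16 inflammatory genes, none of the last 5 lists with a gene lower. Lower were 5 of 13 plasmacytoid DC genes (10 adjusted over the list alone), 8 of 13 MHC class II genes and 6 of 12 genes common to conventional DCs (9 adjusted over the list alone), with Irf8 at -0.87 ± 0.13 and Kmo at -0.98 ± 0.20. H2-Ab1 (-0.89 ± 0.28, adjusted p = 0.0298) lost its call without CSF1 LO replicate 1 (0.115) or 2 (0.0772), or FLT3L LO replicate 1 (0.0540), 2 (0.0707) or 3 (0.0748). Flt3 (adjusted p = 0.121), Zbtb46 (0.0524), Ccr7 (0.223) and Irf4 (0.607) did not pass. The total was 2515 genes, 1791 higher and 724 lower with CSF1, and 2880 in replicates 1 and 2.

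Among HI cells (3 against 3) CSF1 again gave more cell cycle transcripts, but FLT3L gave more of the conventional DC genes. Mcm5 was higher with CSF1 by 1.84 ± 0.17 and Lpl by 2.73 ± 0.44, while Irf8 was lower (-1.56 ± 0.13), as were Cadm1 (-0.64 ± 0.09), Naaa (-1.51 ± 0.20) and Flt3 (-1.72 ± 0.39). S phase genes were higher in 19 of 21 cases and G2/M genes in 8 of 22, or 21 and 11 adjusted over the list alone, with none lower. Of the cDC1 genes, markers of the cross-presenting DC subset, 5 of 15 were lower and 1 higher (11 and 1 adjusted over the list alone), and 9 of 13 MHC class II and 7 of 12 common conventional DC genes were lower (11 and 8 adjusted over the list alone). Outside the cDC1 list, Cd209a (-1.81 ± 0.18), Clec10a (-1.78 ± 0.27) and Mgl2 (-2.46 ± 0.54) were lower too, while S100a4 was higher (1.64 ± 0.33). Macrophage genes did not follow one direction, with 3 higher and 5 lower of 26 (adjusted p = 0.135 with an estimated correlation), since Ms4a7 was lower (-3.54 ± 0.44) and C5ar1 higher (4.94 ± 0.70). H2-Ab1 (-0.98 ± 0.28, adjusted p = 0.0262) lost its call without any 1 of the 6 libraries (0.0564 to 0.0837). Csf1r, Ccr7, Zbtb46, Irf4 and Mafb did not pass (adjusted p from 0.262 to 0.927). In all 1535 genes passed, 824 higher with CSF1, and 1947 within replicates 1 and 2.

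LO cells from stromal cultures differed little from FLT3L LO cells (6 libraries against 3). Lmna, the lamin A gene, was higher with stroma by 6.34 ± 0.50, and the scavenger receptor gene Msr1 by 5.79 ± 0.56. Dusp6, a phosphatase gene induced by MAP kinase signalling, was lower (-3.53 ± 0.24), as were Ccr1 (-3.29 ± 0.22) and Klf4 (-3.46 ± 0.46). Irf8 (0.03 ± 0.11), Flt3 (0.15 ± 0.33), Csf1r (0.20 ± 0.34) and H2-Ab1 (-0.10 ± 0.24) did not pass. Mafb was at 0 counts with FLT3L and at 5.77 ± 3.16 CPM with stroma, at least 65.5-fold higher.

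Monocyte and macrophage genes were higher in 9 of 26 cases and lower in 1 (12 and 1 adjusted over the list alone), among them Fcgr3 at 10.9 ± 7.28 against 0.0575 ± 0.0995 CPM. Lipid handling genes were higher in 5 of 14 cases, with Lpl up by 4.57 ± 0.48 and none lower. G2/M genes were lower in 7 of 22 cases (12 adjusted over the list alone), with an adjusted p = 0.16 with an estimated correlation. Of 6 tested genes of fibroblastic stromal cells only Acta2 passed (4.62 ± 1.11, adjusted p = 0.0205), with pLN LO replicate 1 at 29.32 CPM, and it lost its call within replicates 1 and 2 (0.153) and without FLT3L LO replicate 1 (0.116), 2 (0.0507) or 3 (0.111). The sort for CD45 and CD11c would remove FSC, but RNA carried over from them is not excluded for single genes. Lmna stood at 940.7 ± 256 CPM in CSF1 LO cells, which were cultured without FSC. Zbtb46 was lower (-2.87 ± 0.54). Ccr7 (adjusted p = 0.51) and Irf4 (0.596) did not pass. In total 418 genes passed, 157 higher and 261 lower, 489 within replicates 1 and 2 and 271 without FLT3L LO replicate 1. The G2/M genes Top2a (-1.78 ± 0.33, adjusted p = 0.00229) and Nusap1 (-2.06 ± 0.40, 0.00345) lost their calls without that library (0.104 and 0.139).

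HI cells from stroma differed from FLT3L HI cells (6 against 3) in more genes, with cell cycle genes up and cDC1 genes down. The loss was not particular to cDC1 genes. Outside that list Cd209a (-1.39 ± 0.15) and Clec10a (-0.93 ± 0.22) were also lower, while S100a4 was higher (0.97 ± 0.30) and Mgl2 did not pass (-1.03 ± 0.43). Mcm5 was higher by 2.09 ± 0.16 and Dhfr by 1.96 ± 0.18, both genes of DNA synthesis. Irf8 was lower (-2.31 ± 0.10, 231 ± 31.3 against 1149 ± 23.0 CPM), as were Flt3 (-1.85 ± 0.32), Naaa (-1.96 ± 0.16) and Clec9a (-3.44 ± 0.55), the last a receptor gene of cDC1. Ccl2, a monocyte chemokine gene, was higher by 7.18 ± 1.13 and Lpl by 2.44 ± 0.40. Apoe was lower (-5.47 ± 0.54).

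S phase genes were higher in 20 of 21 cases and G2/M genes in 9 of 22 (12 adjusted over the list alone), with none lower, and the G2/M list had an adjusted p = 0.0806 with an estimated correlation. Of the cDC1 genes 12 of 15 and of the common conventional DC genes 8 of 12 were lower, none higher. Plasmacytoid DC genes were lower in 4 of 13 cases (6 adjusted over the list alone), among them Siglech (-1.97 ± 0.41), in a list that did not pass (adjusted p = 0.103). MHC class II genes were lower in 5 of 13 cases (8 lower and 1 higher adjusted over the list alone; adjusted p = 0.0574 with an estimated correlation), but H2-Ab1 did not pass (adjusted p = 0.0937). Glycolysis genes were higher in 9 of 18 cases and lower in 1, with Tpi1 at 0.94 ± 0.09. Of 6 tested genes of fibroblastic stromal cells only Sparc passed (3.61 ± 1.48 CPM against 0 counts, at least 42.2-fold higher, adjusted p = 0.0268), and it lost its call within replicates 1 and 2 (0.0723) and without FLT3L HI replicate 1 (0.0799), 2 (0.0850) or 3 (0.0774). Csf1r, Ccr7, Zbtb46, Irf4 and Mafb did not pass (adjusted p from 0.116 to 0.885). In total 2478 genes passed, 1178 higher and 1300 lower, and 2792 in replicates 1 and 2.

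Against CSF1, stromal LO cells had lower levels of macrophage and cell cycle transcripts and higher levels of plasmacytoid DC transcripts (6 against 3). Ctsk, a cathepsin gene of macrophages and osteoclasts, was at 0 counts with stroma and 88.3 ± 33.6 CPM with CSF1, at least 2421-fold lower with stroma. Lyz2 (-4.51 ± 0.24), Csf1r (-3.73 ± 0.33), Adgre1 (-3.94 ± 0.32) and Mafb (-3.16 ± 0.59) were lower. The cell cycle genes Birc5 (-4.44 ± 0.33) and Mcm5 (-2.90 ± 0.14) were lower as well. Cd38, which encodes an NAD-consuming surface enzyme, was higher by 3.62 ± 0.30, and Irf8 by 0.90 ± 0.11.

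All 22 G2/M and 20 of 21 S phase genes were lower, as were 13 of 18 glycolysis genes (Pkm -1.75 ± 0.06), none higher in these lists. Monocyte and macrophage genes were lower in 14 of 26 cases and higher in 2, lipid genes lower in 6 of 14 and higher in 2, and inflammatory genes lower in 9 of 16 and higher in 1. Higher were 9 of 13 plasmacytoid DC genes (10 adjusted over the list alone), including Bst2 (0.87 ± 0.10), 6 of 13 MHC class II genes and 6 of 12 common conventional DC genes, with an adjusted p = 0.101 with an estimated correlation for the last. H2-Ab1 (0.78 ± 0.25, adjusted p = 0.0231) lost its call without CSF1 LO replicate 1 (0.110) or 2 (0.0731), and Flt3 (1.05 ± 0.35, 0.0294) without CSF1 LO replicate 1 (0.0946) or 3 (0.161), pLN LO replicate 1 (0.0513) or 2 (0.0513), or mLN LO replicate 1 (0.0505) or 2 (0.0573). Ccr7, Zbtb46 and Irf4 did not pass (adjusted p from 0.237 to 0.847). In total 3584 genes passed, 1194 higher and 2390 lower, and 4016 in replicates 1 and 2.

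Stromal HI cells were close to CSF1 HI cells (6 against 3). Ly6a was higher with stroma by 2.73 ± 0.40 and Ifitm1 by 2.51 ± 0.39, both genes that interferons can induce, and Ddr1, a collagen receptor gene, by 2.28 ± 0.35. Ctsk was lower (-3.23 ± 0.46), as were the fractalkine receptor gene Cx3cr1 (-2.63 ± 0.33) and Irf8 (-0.75 ± 0.11). The fixed lists held few genes that passed, with 1 of 13 MHC class II genes higher (H2-DMb2, 0.51 ± 0.08, whose reads a close paralog may share) and 5 adjusted over the list alone.

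None of 26 DC maturation genes (3 adjusted over the list alone), 21 S phase genes, 19 interferon genes or 16 inflammatory genes passed singly, although camera placed all 4 lists higher with stroma (adjusted p = 1.22e-11, 1.11e-11, 2.73e-06 and 0.000321). The interferon list had an adjusted p = 0.407 with an estimated correlation. Csf1r, Flt3, Ccr7, Zbtb46, Irf4 and Mafb had an adjusted p from 0.758 to 1, and H2-Ab1 (0.39 ± 0.24, adjusted p = 0.787) passed from replicates 1 and 2 only (0.00141). The total was 130 genes, 56 higher and 74 lower. It rose to 310 within replicates 1 and 2 and fell to 67 without CSF1 HI replicate 1, 67 without CSF1 HI replicate 2 and 74 without CSF1 HI replicate 3.

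Stromal libraries were placed on a scale from the FLT3L library (0) to the CSF1 library (1) of the same gate and replicate number, over genes called between the cytokines in libraries of the other numbers. LO libraries lay at 0.121 ± 0.061 (SD, n = 6; range 0.028 to 0.195), next to FLT3L. HI libraries lay at 0.898 ± 0.113 (SD, n = 6; range 0.701 to 1.008), next to CSF1. The means for mLN and pLN were 0.169 and 0.073 in LO and 0.962 and 0.834 in HI cells (n = 3 each), and the mLN library lay above the pLN library of the same number in all 3 cases of each gate, a difference that was not tested. With the libraries numbered 3 left out of the mean, the positions were 0.113 (LO) and 0.855 (HI).

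**Figure D3:**
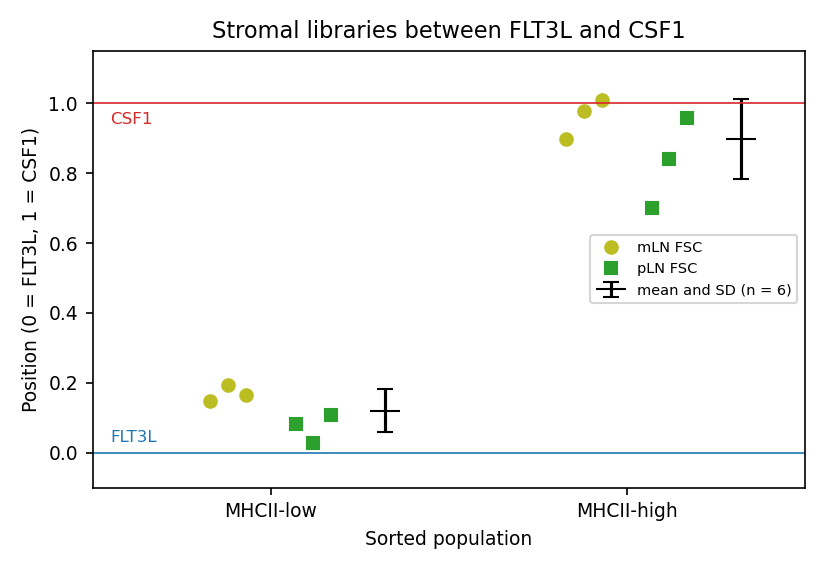
Position of stromal libraries between the cytokines, where each point is 1 library, the vertical axis runs from FLT3L (0) to CSF1 (1) without a unit, and the bars give mean and SD of 6 libraries. The LO libraries lie between 0.028 and 0.195 and the HI libraries between 0.701 and 1.008.

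Few genes were called between cells cultured with mLN and pLN FSC (3 libraries against 3), which does not show that the cells were alike. In LO cells, St3gal5, a ganglioside synthase gene, was higher with mLN FSC by 1.66 ± 0.24, and the mitotic genes Ube2c (2.81 ± 0.50) and Cdk1 (2.32 ± 0.47) were higher as well. Chosen after their values were seen, the chemokine receptor gene Ccr1 (2.07 ± 0.28) and the adaptor gene Dok3 (3.15 ± 0.889 against 0.790 ± 0.303 CPM) were higher too. None of the 8 genes fixed beforehand passed in either gate (each with an adjusted p = 1), and in LO cells Irf8 stood at 6402 ± 370 CPM with mLN and 6961 ± 582 CPM with pLN FSC.

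Of 22 G2/M genes 2 passed, or 12 adjusted over the list alone, all higher with mLN FSC (camera adjusted p = 2.35e-18, and adjusted p = 0.0526 with an estimated correlation). Ube2c and Cdk1 were below 10 CPM, and Ube2c shares 22.8% of its exonic bases with Tnnc2. Both lost their calls within replicates 1 and 2 (0.17 and 0.297), and without pLN LO replicate 1 (0.11 and 0.18) or 3 (0.0979 and 0.131) or mLN LO replicate 1 (0.0811 for both) or 3 (0.0874 and 0.314), Cdk1 also without pLN LO replicate 2 (0.108). In LO cells 22 genes passed, all higher with mLN FSC, 28 within replicates 1 and 2 and 0 in an edgeR fit of the 6 libraries alone, with 623 genes at an unadjusted p under 0.05 in the fit of all libraries and 105 called by DESeq2. The count was 8 without pLN LO replicate 1, 11 without pLN LO replicate 3, 9 without mLN LO replicate 1, 10 without mLN LO replicate 3 and 35 without mLN LO replicate 2.

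In HI cells 1 gene passed (415 at an unadjusted p under 0.05, and 4 called by DESeq2), Ldlrad3 (-2.27 ± 0.35, 1.11 ± 0.357 CPM with mLN and 5.48 ± 3.34 CPM with pLN FSC), named because it was the only one. It lost its call within replicates 1 and 2 (adjusted p = 0.521) and without pLN HI replicate 3 (0.293) or mLN HI replicate 1 (0.0622), 2 (0.389) or 3 (0.408). Acta2, a smooth muscle actin gene, stood at 22.2 ± 4.01 CPM with pLN and 2.54 ± 1.30 CPM with mLN FSC without passing (adjusted p = 1). The DC maturation list was lower with mLN FSC (camera adjusted p = 1.6e-06), with no gene called and an adjusted p = 0.177 with an estimated correlation.

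Each culture and site was also tested alone. Against the input, genes called numbered 4245 (FLT3L LO), 3735 (CSF1 LO), 4634 (mLN LO), 4757 (pLN LO), 5065 (FLT3L HI), 5162 (CSF1 HI), 5457 (mLN HI) and 5500 (pLN HI), or 4614, 4299, 5019, 5260, 5564, 5651, 5942 and 6078 within replicates 1 and 2. Against FLT3L, mLN and pLN FSC gave 287 and 270 genes in LO and 2039 and 1602 in HI cells, and against CSF1 they gave 2658 and 2879 in LO and 54 and 102 in HI cells. Within replicates 1 and 2 these numbers were 356, 321, 2353 and 1667 against FLT3L and 3053, 3314, 137 and 254 against CSF1.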

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

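The comparison of HI-LO effects between stroma and FLT3L with its splits, the tests for HI-gate cells in LO libraries, the tests for the libraries numbered 3 and the fits of replicates 1 and 2 only were chosen only after the result was seen.

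HI-LO effects differed between cultures by tests of the difference itself. They differed for 1018 genes between CSF1 and FLT3L. They differed for 2279 genes between stroma and CSF1 and for 1328 between stroma and FLT3L.

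Other splits of the same samples were drawn for each comparison, and each split was fitted as 2 groups, or as 2 in each gate for HI-LO effects, with only the libraries compared. Over 40 splits each, HI against LO as a mean of cultures gave 8124 genes in the real split and 0 at most in others. LO against input gave 4024 and 1, and HI against input 5794 and 1. Stroma against FLT3L gave 163 and 0 in LO and 2660 and 0 in HI cells. Stroma against CSF1 gave 3051 and 0 in LO and 144 and 4 in HI cells. In each, 1 split was as large, the real one. Other splits mix the groups, so a difference between groups adds to their spread and lowers their counts. A share of 1 in 40 excludes chance only if libraries are independent, which the labels do not say. For the HI-LO effect between stroma and FLT3L the real split also gave the most genes (1205 and 2). Only 40 of 7056 possible splits were drawn there. Splits that follow replicate numbers, as 1 did between stroma and CSF1 below, may be missing from them, so chance is not excluded.

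For HI-LO effects between CSF1 and FLT3L the splits decide nothing, since the 2 others of 40 that made up the 3 with as many genes held all libraries of 1 culture against the other in a gate and so carried that difference (995 genes in the real split, 1030 in the highest other, and 1171 within replicates 1 and 2). Between stroma and CSF1 2 of 40 splits gave as many genes, the real one (2231) and 1 other (2396) that followed replicate numbers within each gate, 1 and 3 against 2 in LO and 1 and 2 against 3 in HI libraries. By this count chance was not excluded, but the other split points to a structure of the samples by number, and 2621 genes passed within replicates 1 and 2. Between mLN and pLN 11 of 40 splits gave at least the 1 gene of the real split, and the highest, with 368, followed the libraries numbered 3, which points to a structure of the samples (7 genes within replicates 1 and 2). Of the 10 other splits as large, 6 held all libraries of 1 site against the other in a gate and so carried that difference. Arms of 3 libraries cannot keep both libraries of every number together, so whether splits followed all numbers could not be asked here.

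The design gives too few splits (10) for a share under 0.05 in comparisons of 3 with 3 libraries. Real and highest other values were 4354 and 0 (HI against LO, FLT3L), 2178 and 0 (CSF1), 5882 and 0 (mLN), 6005 and 0 (pLN), 1817 and 0 (CSF1 against FLT3L, LO), 1487 and 0 (HI), and 0 and 0 for mLN against pLN in LO and HI cells.

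Stromal LO libraries lay near FLT3L and stromal HI libraries near CSF1, with mean positions 0.777 apart. HI-gate cells in the CSF1 LO libraries would bring their maturation genes along. Monocyte and macrophage genes gave a median share of 59.4% HI-gate RNA (quartiles 48.4 to 139.5, 17 genes), but DC maturation genes 0.611% (0 to 14.6, 22 genes). Each gene was over 1 CPM higher in CSF1 HI than in FLT3L LO. These shares argue against this source, while how cleanly the MHC class II gate kept such cells out was not tested. With libraries thinned to 9822686 counts the positions were 0.797 apart, and 0.742 apart with the libraries numbered 3 left out of the mean, or 0.741 with them left out of the choice of genes too, so depth and those libraries were not the cause either. A difference in the cells with each culture stays open as a hypothesis found and tested on the same data.

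Camera placed the G2/M genes higher in mLN LO than in pLN LO cells, with a median log2 change of 1.33, but 2 of 22 members passed and the list had an adjusted p = 0.0526 with an estimated correlation. Without 1 of the 6 libraries the median was 0.98 to 2.35, so no single library made it, but 0 members passed in edgeR without pLN LO replicate 1 or 3 or mLN LO replicate 1 or 3. The excess was 4.78% of the level in mLN HI cells, but 14 DC maturation genes of at least 16 CPM in mLN HI and with a low level in pLN LO stood in mLN LO at a median of 1.148% of their mLN HI level (quartiles 0.352 to 2.32, against 3.42 to 6.27 for the G2/M excess), with Ccl22 at 0 against 444 CPM and Ccr7 at 8.31 against 594 CPM, which argues against HI-gate cells of the mean mLN HI profile. Over the 22 DC maturation genes that passed as higher in mLN HI than in mLN LO cells the share was -0.531% with the pLN LO level subtracted and 4.04% without (median 1.42%). The share without subtraction missed the bound set first, 0.1 of 4.78%. The medians of 1.42% and, for the 14 genes with a low level in pLN LO, 1.148% missed it too. HI-gate cells rich in G2/M and poor in maturation transcripts and a difference between lymph node sites cannot be told apart, because no table holds such cells alone.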

How the results depend on the processing

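The setting of replicates 1 and 2 only, and the HI-LO effect of stroma against FLT3L, were chosen after the data were seen. RLE scaling and no low count filter left every count of called genes within 1.5 times its value. No named gene or list test reversed where its direction was compared. Directions were not compared for list tests with replicates 1 and 2 only, nor for single genes of HI-LO effects. Stromal positions went from 0.121 (LO) and 0.898 (HI) to 0.131 and 0.878 with genes past an absolute log2 change of 1. The pseudocount alternative was not run, since counts were used. Of 480 results of named genes 406 passed, 76 changed their side of the threshold under some alternative and 0 reversed.

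With the replicate number as a block, counts rose to 3756 (HI against LO, CSF1), 2668 (CSF1 against FLT3L, HI), 685 and 3911 (stroma against FLT3L, LO and HI) and 348 (stroma against CSF1, HI). HI-LO effects gave 1540 (CSF1 against FLT3L), 6 (mLN against pLN) and 2390 (stroma against FLT3L). Against FLT3L, mLN gave 491 (LO) and 3368 (HI) and pLN 492 and 2771, and against CSF1 in HI cells they gave 142 and 281. Of 27 libraries 21 correlated best with a library of their own number. Correlations were positive for all 108 pairs of the same number (0.018 to 0.347, median 0.184), against a median of -0.108 for different numbers. Libraries of a number therefore shared a structure, weakest for number 1 (median 0.066) and strongest for number 3 (median 0.252). The main fit does not model it, and what a number stands for is not known.

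DESeq2 gave 705 (stroma against FLT3L, LO), 310 (stroma against CSF1, HI), 105 and 4 (mLN against pLN, LO and HI), 35 (their HI-LO effect), 564 and 569 (mLN and pLN against FLT3L, LO), and 147 and 256 (mLN and pLN against CSF1, HI). Replicates 1 and 2 only gave 310 (stroma against CSF1, HI), 0 (mLN against pLN, HI), 7 (HI-LO effect), 137 and 254 (mLN and pLN against CSF1, HI). A fit of only the libraries compared gave 128 (stroma against FLT3L, LO), 0 and 0 (mLN against pLN, LO and HI), 1 (HI-LO effect), 49 and 30 (mLN and pLN against FLT3L, LO) and 26 (mLN against CSF1, HI). List tests that passed went from 190 to 96 with an estimated correlation. The cause was not tested.

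Leaving out 1 library gave 271 to 465 (stroma against FLT3L, LO), 67 to 148 (stroma against CSF1, HI), 8 to 35 and 0 to 1 (mLN against pLN, LO and HI) and 0 to 10 (their HI-LO effect), which called 2 without pLN LO replicate 1, 10 without 2, 2 without 3 and 1 without mLN LO replicate 1. The 67 came without CSF1 HI replicate 1 or 2 and 74 without 3, the 271 without FLT3L LO replicate 1. For mLN against pLN, LO, the values were 8 and 11 without pLN LO replicate 1 and 3, and 9, 35 and 10 without mLN LO replicate 1, 2 and 3, and in HI cells 0 without pLN HI replicate 3 or mLN HI replicate 1, 2 or 3. It gave 26 to 36 (mLN against CSF1, HI), with 33, 26 and 32 without mLN HI replicate 1, 2 and 3 and 32 and 33 without CSF1 HI replicate 1 and 2. It gave 42 to 82 (pLN against CSF1, HI), with 42 and 60 without pLN HI replicate 1 and 2 and 43, 46 and 57 without CSF1 HI replicate 1, 2 and 3. It gave 886 to 1307 (pLN against FLT3L, HI), with 886 without pLN HI replicate 3 and 1045 without FLT3L HI replicate 2. Depth limits calls near 0 counts, where folds are lower bounds.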

Other observations

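The tests below were all chosen after the data were seen.

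Genes that passed against both FLT3L and CSF1 in the same direction were counted in stromal cells. In LO cells 41 were higher and 191 lower, and in HI cells 21 and 37. Counts simulated without any difference between groups gave 0 at most in 10 runs of edgeR, which does not give the overlap to be had from comparisons that share the stromal libraries and each hold differences. Higher in both gates were 8 genes, Casp6, Cd38, Flot1, Ier3, Jak3, Myd88, Relt and Socs3, and lower was Lmo1. Socs3, a feedback inhibitor gene of cytokine receptors, stood at 87.9 CPM in stromal LO cells against 16.2 with FLT3L (log2 difference 2.44 ± 0.26) and 15.2 with CSF1 (2.52 ± 0.27).

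Because Socs3 and Jak3 were among them, signalling through JAK-STAT receptors was tested as a hypothesis on 93 genes of the KEGG pathway, after all 197 pathways had been tested in each gate, where 17 passed in LO and 20 in HI cells, or 0 and 8 with an estimated correlation. The pathway did not pass in LO cells (12 genes higher and 12 lower, camera adjusted p = 0.611, and adjusted p = 0.901 with an estimated correlation) or in HI cells (9 and 8, 0.991 and 0.998). The prediction of higher levels for the pathway as a set was thus not met. Camera looks for a shared direction of transcripts and cannot see changes that go both ways, so it does not decide on signalling itself.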
